A study of Mus musculus with 6 samples.

How the data were processed

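Spinal cord RNA of 3 TSCI and 3 sham libraries was analysed from 2 deposited tables. Per the labels' protocols, RNA was extracted with Trizol, ribosomal RNA was depleted and stranded total RNA libraries were made. The submitters' processing notes name HISAT2, StringTie and TopHat, without versions. The caller of circRNAs and the genome build are not given in the sources used here. Of the Ensembl transcript IDs found in GENCODE M21 (GRCm38), 94.6% had the same chromosome, start and end in the table, so coordinates are given as GRCm38; annotated gene positions and classes come from GENCODE M21, which matched 99.7% of gene names.

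The isoform table held 194125 isoforms with FPKM and coverage (signal) values, as deposited by the authors. Of these, 115585 were assembled isoforms without an Ensembl ID, among them 66485 within introns. FPKM divided by coverage was constant within a library and gave the aligned bases. The circRNA table held deposited counts and deposited FPKM of circRNAs. The deposited circRNA counts were treated as estimated counts, since only 33.8% were whole numbers (within 1e-06), and at host genes with 1 circRNA 88.7% were. What was counted as a circRNA read is not given in the sources used here. The values were rounded to whole numbers before testing. The design had foreseen whole junction reads or normalized values, and the test for counts was kept. No treatment with RNase R is named in the labels. All per-sample columns were matched to samples by name.

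Gene values were the sum of the FPKM of isoforms with the same gene name, as planned, which includes intronic and antisense isoforms. Tests used limma 3.58.1 with a mean-variance trend on log2(FPKM + 0.5), for genes or isoforms with a mean FPKM of at least 0.5 over the 6 libraries, with Benjamini-Hochberg adjustment and a threshold of 0.05. A fold change on this scale understates the change of low genes. FPKM were not rescaled. An exact 0 can be a failed estimate, so genes with a library at 0 are given by library. The prior degrees of freedom were 9.7 for genes and infinite for isoforms. Isoform usage was tested with diffSplice, and gene lists with camera (preset correlation 0.01, at least 4 tested genes), camera with an estimated correlation, and fry. The 34 lists covered cell types of the cord, tissue around it, and responses to injury, and some share genes. circRNAs with at least 10 counts over the 6 libraries and presence in at least 3 were tested with edgeR 4.0.16 (TMM, quasi-likelihood), with DESeq2 1.42.0 as an alternative. Single values were compared by exact permutation, which cannot go below p = 0.1 with 3 against 3. R 4.3.3 and Python 3.11.15 were used.

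Named genes followed a rule set before the data were examined: the 10 largest rises and falls among passing genes whose groups do not overlap with at least 1 FPKM in a group, up to 3 members of lowest p per list, 6 rises and 6 falls of lncRNA genes, 5 and 5 of isoforms, the 5 usage genes of lowest p, 8 and 8 passing circRNAs or, with fewer than 4 passing, the 5 of lowest p in each direction, and 6 textbook markers. Some items that this rule takes are not reported here. Alternatives fixed at the same time were other pseudocounts, filters and scalings, array weights, the replicate number or the lane as a covariate, and each library left out. Alternatives chosen after seeing the data were lane 8 alone as a covariate, the libraries of the other lanes only, reference-class isoforms only (class codes =, j, c, o and e, which keep assembled isoforms with new junctions and leave out intronic, antisense and nearby ones), class = isoforms only, robust or no moderation of variances, other circRNA scalings and sums, and Gene Ontology terms.

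The functions were tested on simulated data with 34 changed genes per size among 19072. With variances drawn from the fitted prior, 64.7% of genes raised by a log2 fold change of 6 were recovered, 23.5% at 4 and 0% at 2, and 3 unchanged genes were called; with each gene's own residual variance the shares were 55.9%, 8.8% and 2.9%. For isoforms the shares at 6 were 29.4% with the fitted prior and 0% with own variances. For isoform usage, with own variances, 47 unchanged genes were called beside 89 of 100 genes changed by 8. For circRNAs 76.5% were recovered at 4. Changes of 4-fold (2 on the log2 scale) in single genes were therefore mostly not detectable with these libraries.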

Results

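RNA was profiled in the spinal cord of male C57BL/6 mice, an inbred laboratory strain, aged 8 weeks. The TSCI libraries came from mice given a traumatic spinal cord injury by a dropped weight, and the sham libraries from mice whose vertebral arch was opened without the injury (laminectomy). Each group had 3 libraries. The labels name 48 mice in sets of 8 but do not say whether the mice of a set were pooled. Nor do they say how long after injury the tissue was taken. The p-values below are therefore not taken to measure a spread between mice. Those of single genes rest on the spread between these libraries, drawn toward a trend over all genes (prior degrees of freedom 9.7). For circRNAs they rest on that spread too, with the variance moderated over all circRNAs. Those of isoforms rest on a variance pooled over isoforms, and camera sets the genes of a list against the other genes. The aligned bases implied by the deposited FPKM and coverage were 4.46, 7.93 and 9.16 gigabases in TSCI replicates 1 to 3 and 5.93, 4.8 and 8.2 gigabases in sham replicates 1 to 3. The libraries differed in ways the groups do not explain. TSCI replicate 1 and sham replicate 1, both from sequencing lane 8, had 9.8% and 10.2% of their bases in intronic isoforms, against 2.0% to 3.8% in the other libraries. Sham replicate 2, from lane 3, listed 3765 of the 19072 tested genes at 0, against 664 to 1533 in the others. No pair of libraries was a duplicate: the highest Spearman correlation of gene values was 0.87, between TSCI replicates 2 and 3. By these correlations the libraries did not group by injury alone. TSCI replicate 1 and sham replicate 1 each correlated best with the other (0.75), and sham replicate 3 with TSCI replicate 2 (0.77). Sham replicate 2 correlated best with sham replicate 3 (0.73).

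The first comparison asked which genes differed between injured and sham cord. Hmox1, the heme-degrading enzyme heme oxygenase 1 (ENSMUSG00000005413, chromosome 8, 75093621 to 75100589), had 304 ± 144 FPKM in TSCI and 2.02 ± 1.19 in sham (SD, n = 3 each), a log2 fold change of 6.88 ± 0.73 (SE; limma, adjusted p = 0.00461). Arg1, an arginine-degrading enzyme of macrophages (ENSMUSG00000019987, chromosome 10, 24915221 to 24927484), had 148 ± 113 FPKM against 0.813 ± 1.12, a log2 fold change of 6.80 ± 0.86 (SE; limma, adjusted p = 0.0102). Serpina3n, a protease inhibitor of reactive astrocytes, had 406 ± 158 FPKM against 8.06 ± 7.37. Msr1, a scavenger receptor, had 56.1 ± 30.0 against 0.429 ± 0.215.

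In all, 24 of 19072 genes passed an adjusted p of 0.05 in limma, and all 24 were higher in TSCI. No gene passed as lower in this fit; at an unadjusted p under 0.05 there were 1371 higher and 187 lower genes. The groups did not overlap in 14.1% of genes, where chance gives 10% if no group is shifted as a whole. All TSCI values lay above all sham values in 2234 genes and below them in 447. The median log2 fold change of all genes was 0.47. The share thus cannot tell a shift of all genes from changes in single genes. Other genes among the largest rises had at least 1 sham library listed at 0. Gpnmb, a glycoprotein of lipid-laden phagocytes, was at 44.5, 27.1 and 46.9 FPKM in TSCI replicates 1 to 3 and at 0.913, 0 and 0.004 in sham replicates 1 to 3. Lilrb4a, an inhibitory receptor of myeloid cells, was at 55.7, 24.6 and 42.4 against 0.601, 0 and 0.466. An isoform counted in it, at 35.5, 10.9 and 18.5 FPKM in TSCI, reaches over the neighbouring gene Lilr4b. Part of the Lilrb4a value may therefore belong to Lilr4b. Tgm1, a transglutaminase, was at 58.7, 17.7 and 22.0 against 0.093, 0 and 0.252. The histone gene Hist1h2bg (30.4, 6.47 and 73.2 FPKM) and the small nucleolar RNA Gm25835 (22.2, 42.3 and 11.5 FPKM) were listed at 0 in every sham library. Histone genes have near-identical copies, so the value of Hist1h2bg is uncertain. Gm25835 lies within an Eif4a1 isoform on the same strand, so its value may hold reads of that isoform. The Eif4a1 isoform was at 73.0, 53.2 and 95.0 FPKM in TSCI and 0.211, 0 and 0.159 in sham. The other passing genes included Timp1 (90.1 ± 2.43 against 2.19 ± 1.95 FPKM), Spp1 (543 ± 285 against 15.7 ± 11.2) and the chemokine Ccl7 (22.1 ± 6.69 against 0.296 ± 0.314).

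**Figure D1:**
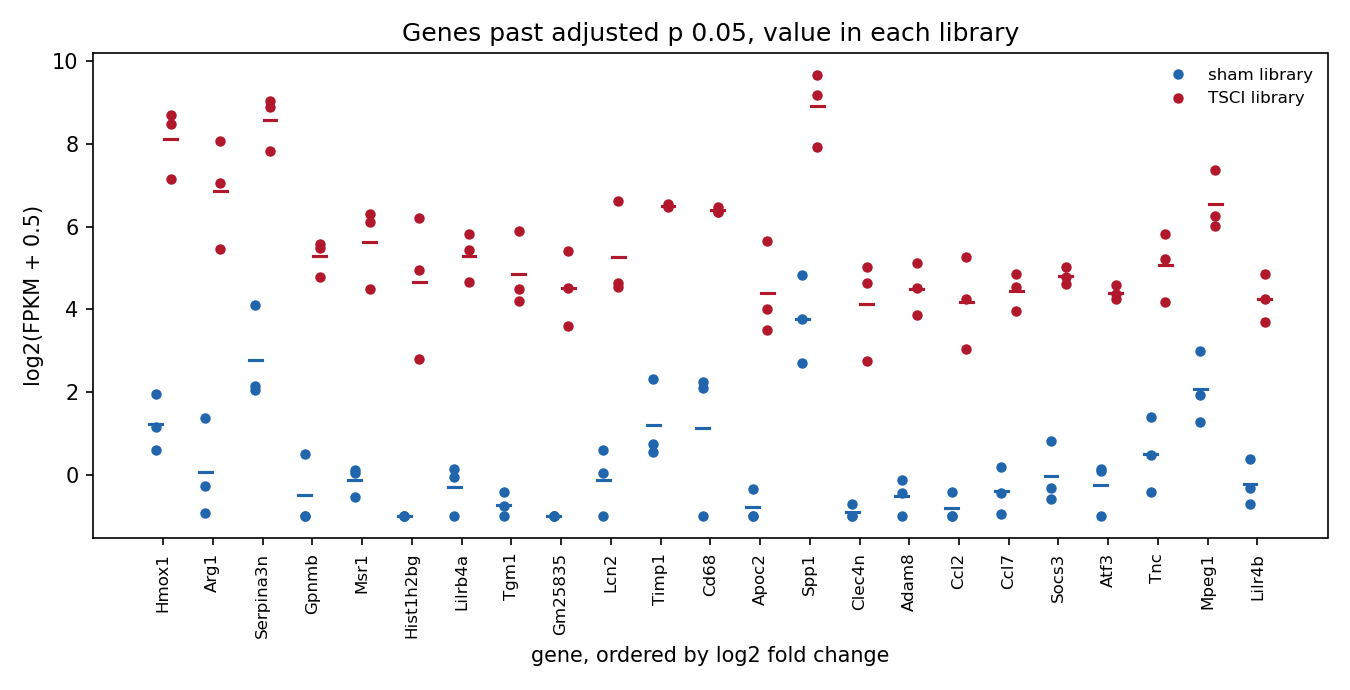
Values in each library of genes past adjusted p 0.05, as log2(FPKM + 0.5), with sham libraries in blue, TSCI libraries in red and a bar at each group's mean. All 3 TSCI values lie above all 3 sham values in each gene drawn, and points at the bottom of the sham columns are values listed at 0.

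Within lane 8, which held 1 library of each group, Hmox1 had a log2 fold change of 6.55, and within lane 1, which held 2 TSCI libraries and 1 sham library, it had 7.31. For Arg1 these values were 5.73 and 8.50. Lane 3 held a sham library only. As deposited, the median log2 fold change of all genes was 0.47; it was 0.09 after median-ratio scaling and -0.02 after quantile normalization. Relative to that median, Hmox1 was 6.41 higher and Arg1 6.34 higher. The Arg1 call was lost with median-ratio scaling (limma, adjusted p = 0.0737), quantile normalization (0.0581) and no lane 8 libraries (0.106), with log2 fold changes of 6.41, 6.14 and 7.34. The Msr1 call was lost with both scalings (0.0685 and 0.0593), with log2 fold changes of 5.33 and 5.08. So were the calls for Timp1 (0.0703 and 0.0519), Spp1 (0.0708 and 0.0696), Ccl7 (0.0737 and 0.0781) and Cd68 (0.0981 and 0.0624). Those for Ccl2 (0.0618 and 0.0521), Atf3 (0.0685 and 0.0519), Hist1h2bg (0.0618 and 0.0519) and Gm25835 (0.0618 and 0.0517) were lost too. In these genes, from Timp1 to Gm25835, the log2 fold changes were 4.38 to 5.38 and 4.18 to 5.34, against 4.65 to 5.65 as deposited. The call for Tnc was lost with median-ratio scaling (0.0521), with a log2 fold change of 4.26. Hmox1 passed with median-ratio scaling, quantile normalization and no lane 8 libraries (0.0124, 0.0135 and 0.0437), as did Serpina3n (0.0288, 0.0365 and 0.0353). Msr1 passed with no lane 8 libraries (0.0458). Every other passing gene lost its call there, among them Gpnmb (0.111), Lilrb4a (0.162), Tgm1 (0.188) and Lcn2 (0.188). In these the log2 fold changes with no lane 8 libraries were 6.17, 5.56, 5.05 and 5.07. The number of genes past the threshold was not stable. It fell to 8 after median-ratio scaling, all higher, and to 0 with all lanes as a covariate or with each gene's own variance. It was 273 (263 higher, 10 lower) with lane 8 alone as a covariate and 149 (147 higher, 2 lower) from reference-class isoforms only. With array weights (13.56 for sham replicate 3, 0.08 for TSCI replicate 3, others 0.59 to 1.69) it was 165 (149 higher, 16 lower). With no lane 8 libraries it was 8 (4 higher, 4 lower). Without TSCI replicate 1, 2 or 3 it was 0, 1 and 0, and without sham replicate 1, 2 or 3 it was 26 (22 higher, 4 lower), 3 and 9.

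Gene lists fixed before the data were examined were then compared, each against all other genes. By camera with a preset correlation, 25 of 34 lists passed an adjusted p of 0.05, 18 of them higher in TSCI and 7 lower. With an estimated correlation 3 lists passed, and these were the monocyte and macrophage, the phagocyte and the chemokine lists, each at adjusted p = 0.0403. By fry, which does not compare a list with other genes, 15 lists passed, all higher. Without sham replicate 1, 16 lists passed by camera.

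All 16 monocyte and macrophage genes had positive fold changes, with a median log2 fold change 2.33 above that of all genes; 12 passed when adjusted over the list alone and 1, Arg1, over all genes. Cd14, a receptor for bacterial lipopolysaccharide, had 20.1 ± 6.70 FPKM against 0.918 ± 0.331, and S100a4 had 97.9 ± 88.4 against 6.33 ± 8.52. Of 18 genes of lysosomes and phagocytic microglia, 11 passed when adjusted over the list alone and 3 over all genes (Gpnmb, Spp1 and Cd68). Cd68 was at 81.6, 80.6 and 88.6 FPKM in TSCI and at 3.80, 0 and 4.25 in sham. Of 21 chemokines and cytokines, 14 passed when adjusted over the list alone and 2 over all genes; Ccl2, which attracts monocytes, was at 38.2, 18.4 and 7.66 FPKM against 0.250, 0 and 0. The 3 lists held in each lane with both groups: over their 55 tested genes the median was 2.23 above that of all genes within lane 8 and 2.19 within lane 1. The calls with an estimated correlation were lost with lane 8 as a covariate (adjusted p = 0.0691 each), without sham replicate 2 (0.111 each) and without both lane 8 libraries (0.355 each). The macrophage and phagocyte calls were also lost with median-ratio scaling (0.117 and 0.108) and from reference-class isoforms only (0.0585 each), where the chemokine call was not (0.0235 and 0.0274). Erythrocyte genes moved with them, with a median 1.24 above that of all genes (camera, adjusted p = 0.0273; adjusted p = 0.263 with an estimated correlation) and 1 of 7 past the threshold adjusted over the list alone, Alas2 (148 ± 102 against 17.6 ± 11.7 FPKM). The erythrocyte call was lost with median-ratio scaling (camera, adjusted p = 0.0915), and without TSCI replicate 2, TSCI replicate 3 or sham replicate 1 (0.205, 0.139 and 0.262).

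Other immune lists were higher by camera, but not with an estimated correlation. Neutrophil genes (4 of 11 past the threshold adjusted over the list alone, 1 over all genes; adjusted p = 0.0696 with an estimated correlation) included Lcn2, an iron-binding protein that reactive astrocytes also make, at 97.6, 22.7 and 24.3 FPKM against 1.01, 0 and 0.521. Complement genes (4 of 14 adjusted over the list alone, 0 over all genes; adjusted p = 0.0559 with an estimated correlation) included the receptor C3ar1, at 18.7 ± 9.41 FPKM against 0.313 ± 0.286. Innate sensors (9 of 15 adjusted over the list alone, 0 over all genes; adjusted p = 0.132 with an estimated correlation) included Tlr13, at 11.3 ± 2.53 against 0.866 ± 0.325. Interferon response genes had 2 of 15 past the threshold adjusted over the list alone (adjusted p = 0.124 with an estimated correlation), and antigen presentation genes had 0 of 13 (adjusted p = 0.208 with an estimated correlation). Homeostatic microglia genes had 2 of 12 adjusted over the list alone, Fcrls (83.3 ± 38.5 against 4.29 ± 2.58 FPKM) and Tmem119 (24.0 ± 9.18 against 4.86 ± 3.11), and 0 over all genes (adjusted p = 0.208 with an estimated correlation). Without sham replicate 1 the calls for interferon response, antigen presentation and homeostatic microglia genes were lost (camera, adjusted p = 0.114, 0.221 and 0.268). Without TSCI replicate 2 those for antigen presentation and homeostatic microglia genes were lost (0.0806 and 0.148), and without TSCI replicate 3 that for homeostatic microglia genes (0.0604), which lane 8 as a covariate (0.104) and median-ratio scaling (0.131) ended too.

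Cell division genes had the highest median of the 34 lists, 2.57 above that of all genes. Of these 18 genes, 17 passed when adjusted over the list alone and 0 over all genes (camera, adjusted p = 7.55e-20; adjusted p = 0.0559 with an estimated correlation). The topoisomerase Top2a had 22.4 ± 8.62 FPKM against 0.790 ± 0.661, and the kinase Cdk1 was at 10.4, 19.3 and 20.7 against 0.088, 0 and 1.02. Reactive astrocyte genes had 12 of 18 past the threshold adjusted over the list alone and 4 over all genes (adjusted p = 0.0893 with an estimated correlation, 0.0235 after median-ratio scaling). Vim, an intermediate filament of reactive astrocytes and other cells, had 542 ± 164 FPKM against 35.3 ± 6.70 (log2 fold change 3.89 ± 0.79, SE; limma, adjusted p = 0.0760). Gfap, the astrocyte filament, had 506 ± 467 against 277 ± 254 and did not pass (limma, adjusted p = 0.881). Extracellular matrix genes had 6 of 18 adjusted over the list alone and 1 over all genes, Tnc (36.9 ± 19.2 against 1.10 ± 0.958 FPKM; adjusted p = 0.14 for the list with an estimated correlation). Genes of the neuronal injury response had 6 of 14 adjusted over the list alone and 1 over all genes (adjusted p = 0.262 with an estimated correlation), the transcription factor Atf3, at 18.5, 20.1 and 23.5 FPKM against 0.572, 0 and 0.601. Lists of p53 and apoptosis (6 of 14 adjusted over the list alone, 0 over all genes), immediate early genes (2 of 14, 1), stress and heat shock (2 of 14, 1) and endothelium (0 of 13, 0) were also higher by camera. With an estimated correlation their adjusted p was 0.125, 0.341, 0.269 and 0.469. The endothelial call was lost without TSCI replicate 3 or sham replicate 3 (camera, adjusted p = 0.0895 and 0.135).

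Neuronal lists were lower than other genes by camera, though no member passed when adjusted over its list alone. Relative to the median of all genes, the median was lower in genes of synaptic receptors (-1.08; 15 of 18 members with negative fold changes), excitatory neurons (-1.08), ion channels (-0.89), inhibitory neurons (-0.80) and neurons in general (-0.72). With an estimated correlation their adjusted p was 0.36, 0.167, 0.476, 0.469 and 0.425. Grin2b, a glutamate receptor subunit, had 1.5 ± 0.308 FPKM in TSCI and 13.4 ± 12.4 in sham. Eno2, the neuronal enolase, had 62.2 ± 18.0 against 140 ± 38.7, and Rbfox3, the neuronal nuclear antigen, had 4.35 ± 0.869 against 10.8 ± 8.25; none of the 3 passed. Homeostatic astrocyte genes were also lower by camera (median -0.81 relative to all genes, 0 of 14 adjusted over the list alone; adjusted p = 0.432 with an estimated correlation), among them Slc6a11, a GABA transporter, at 7.27 ± 5.87 against 32.3 ± 27.8 FPKM. Skeletal muscle genes had the lowest median of the 34 lists, -2.28 relative to all genes (0 of 12 adjusted over the list alone; adjusted p = 0.221 with an estimated correlation). Myoglobin, Mb, was at 1.80, 17.8 and 8.53 FPKM in sham replicates 1 to 3 and at 0, 2.10 and 0.052 in TSCI. The median log2 fold change of the synaptic list was -1.71 within lane 8 and -0.24 within lane 1, and that of the muscle list -0.43 and -1.58. Without sham replicate 1 the calls for neurons in general, ion channels, excitatory neurons, inhibitory neurons and homeostatic astrocytes were lost (camera, adjusted p = 0.116, 0.384, 0.1, 0.344 and 0.169). Without TSCI replicate 3 those for excitatory and inhibitory neurons were lost (0.0544 and 0.0835). With no lane 8 libraries those for neurons in general, ion channels and inhibitory neurons were lost (0.111, 0.0814 and 0.151), and from reference-class isoforms only that for homeostatic astrocytes (0.0711).

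The 9 remaining lists did not pass by camera. These were cholesterol synthesis, ependymal cells, known lncRNAs, lymphocytes, motor neurons, myelin, oligodendrocyte precursors, pericytes with smooth muscle, and Schwann cells. Among their members, 2 passed when adjusted over the list alone, the smooth muscle genes Tagln (190 ± 111 against 8.35 ± 3.89 FPKM) and Acta2 (12.9 ± 3.98 against 2.35 ± 0.797). Motor neuron, Schwann cell and known lncRNA genes had positive median fold changes (0.03, 0.29 and 0.33) but lay below the median of all genes, and camera placed them lower. The mean of the Schwann cell list was -0.11. Cholesterol synthesis genes had a median of 0.47 and a mean of 0.36, and camera placed them lower; ependymal genes had a median of -0.08 and a mean of 0.01. Without TSCI replicate 2 the ependymal list passed as lower (camera, adjusted p = 0.0203), and without TSCI replicate 1 the Schwann cell list did (0.0343). With all lanes as a covariate the motor neuron and ependymal lists passed (0.0191 and 0.0365), with array weights that of oligodendrocyte precursors (0.0451), and from reference-class isoforms only the Schwann cell list (0.0346). Mbp, the myelin basic protein, had 1336 ± 1350 FPKM in TSCI and 1666 ± 2078 in sham. Aif1, the microglial marker Iba1, had 13.8 ± 9.65 against 6.02 ± 2.41 and did not pass (limma, adjusted p = 0.806).

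**Figure D2:**
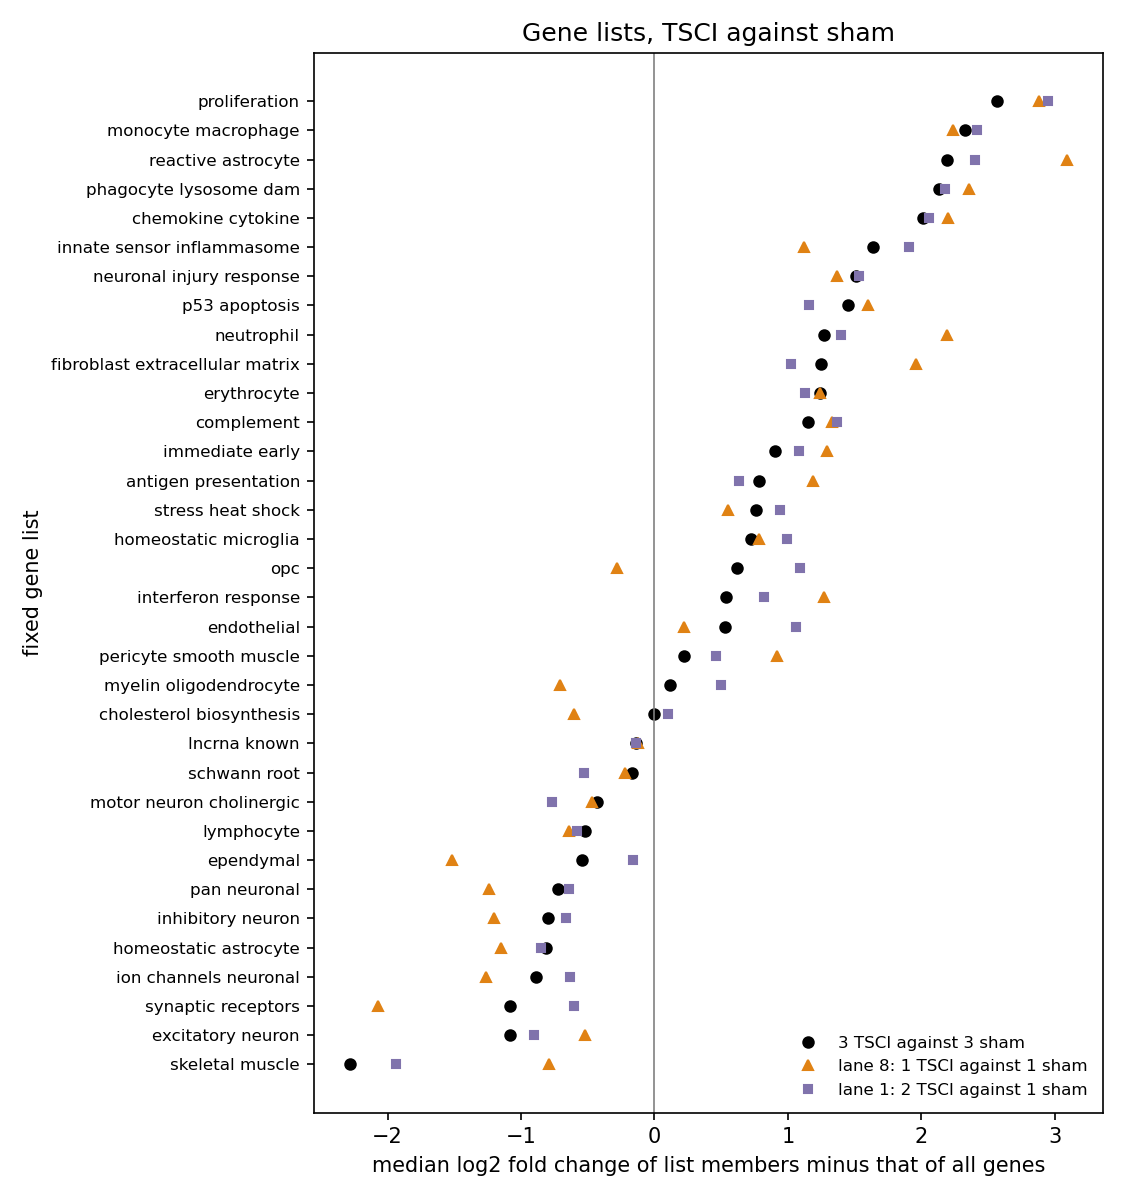
Median log2 fold change of each fixed gene list minus that of all genes, TSCI against sham. Black points use all 6 libraries, triangles lane 8 (1 library of each group) and squares lane 1 (2 TSCI libraries, 1 sham library). Cell division genes lie highest at 2.57 and skeletal muscle genes lowest at -2.28. The myelin, oligodendrocyte precursor and cholesterol synthesis lists lie on different sides of 0 in the 2 lanes.

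The series was made to profile noncoding RNA, so long noncoding RNA (lncRNA) genes were compared next. No lncRNA gene of 2684 passed in limma, whether adjusted over these genes alone or over all genes. An unadjusted p under 0.05 was found for 108 of them. That share lies below 0.05 and below the share over all genes (1558 of 19072). Of the known lncRNAs, Snhg1, a host gene of small nucleolar RNAs, was at 11.5, 32.3 and 16.8 FPKM in TSCI and 1.996, 0 and 5.57 in sham. The imprinted H19 had 47.3 ± 33.6 against 7.07 ± 2.28, and Pantr1 had 3.13 ± 1.14 against 18.1 ± 16.6. Chosen after the values were seen, AI506816 had the lowest p (38.2 ± 19.9 against 2.44 ± 0.868 FPKM; limma, adjusted p = 0.0722 over all genes). The lowest p among lower lncRNA genes was that of 0610043K17Rik (0.959 ± 0.159 against 13.01 ± 6.91 FPKM). With array weights 4 lncRNA genes passed over all genes, with lane 8 as a covariate 9, and from reference-class isoforms only 4.

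Single isoforms were compared in the same way, and the number of isoforms past the threshold was 186 of 89293 in limma, 152 higher and 34 lower, from 166 named genes. This count needs care, because the fitted prior gave infinite degrees of freedom, so that every isoform was tested against a pooled variance and not its own spread. With each isoform's own variance 17 passed, 15 of them higher. Of the lower isoforms, 8 were listed at 0 in every TSCI library, and of the higher ones 31 in every sham library. An isoform of Lgals3, the galectin of phagocytes (ENSMUST00000150290, chromosome 14, 47373899 to 47385799), was at 45.5, 448 and 223 FPKM in TSCI and 0.805, 0 and 0 in sham. The Arg1 isoform ENSMUST00000020161 was at 43.5, 156 and 132 FPKM in TSCI and listed at 0 in every sham library. The other largest rises among isoforms whose groups did not overlap were an assembled isoform of Vim (620, 282 and 538 against 32.7, 0 and 0), one reaching from Hba-a1 to the near-identical Hba-a2 (989.5, 190 and 2487, listed at 0 in sham), and that of Gm22634 (278, 19652 and 1081 against 271, 0 and 0). Among falls whose groups did not overlap, the largest were isoforms of Gm24616, Gphn, Stau2, Phf21a and Hist1h4i; that of Stau2, an RNA-binding protein, was at 0, 8.80 and 1.63 FPKM in TSCI and 24.7, 115 and 146 in sham. Without TSCI replicate 1, 2 or 3 the count was 5, 20 and 81, without sham replicate 1 it was 413, and with lane 8 as a covariate it was 0.

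Of 12060 genes tested for isoform usage (limma diffSplice), the number of isoform usage genes past the threshold was 0, and 683 had an unadjusted p under 0.05. The lowest adjusted p was 0.0516, for Lgals9, followed by Pgd and Vim (0.0611 each) and Gpr34 and Pmm2 (0.13 each). In Lgals9, ENSMUST00000108268 was at 16.0, 9.06 and 19.9 FPKM in TSCI and 0.675, 0 and 0 in sham, and ENSMUST00000108269 was at 0.299, 0.032 and 0.027 against 4.46, 2.07 and 2.96. Without sham replicate 1, 47 genes passed, without TSCI replicate 1, 12, and without TSCI replicate 2, TSCI replicate 3 or sham replicate 3, 1 each.

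The last comparison was of circular RNA (circRNA), RNA closed into a ring, mostly by back-splicing. By the deposited types, 16816 were circRNA and 624 were ciRNA, and both are called circRNA here and were tested together. The table listed 17440 circRNAs from 5334 host genes, with 4117695, 4311016 and 6877068 counts in TSCI replicates 1 to 3 and 7177607, 6028019 and 4218762 in sham replicates 1 to 3. These were 10.8% to 18.9% of the library totals that the circRNA FPKM imply. In all 38178 comparisons of nested circRNAs with a shared start, the longer had at least the count of the shorter. Counts of nested circRNAs are therefore not independent of each other. The counts and the CPM below can thus hold reads other than those over a circRNA's own back-splice junction. No difference in the total was detectable, with a ratio of TSCI to sham means of 0.878 (n = 3 each; exact permutation test, two-sided, p = 0.6, smallest possible 0.1). The number of circRNAs above 0 was 17140, 17370 and 17377 in TSCI and 17333, 15617 and 17050 in sham (exact permutation test, two-sided, p = 0.2).

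The number of circRNAs past the threshold was 0 of 17363 in edgeR's quasi-likelihood test, where 2022 had an unadjusted p under 0.05; DESeq2 called 251, 199 higher and 52 lower, and edgeR with all lanes as a covariate called 75. Among circRNAs of low p, none of which passed in edgeR, a circRNA of Tgfbi (chromosome 13, 56627914 to 56632989) had 262 ± 24.1 CPM (counts scaled by library size) in TSCI and 19.7 ± 5.05 in sham, and one of the kinase gene Lyn had 107 ± 25.0 and 12.6 ± 1.08. Those of Iqgap1 and Ly9 followed. The lowest p among lower circRNAs were those of Prmt8 (2.33 ± 0.812 against 16.9 ± 3.38 CPM), Ryr2, Col19a1, Brinp1 and Ptprr; none passed. Within lane 8 and within lane 1 the log2 fold change of the Tgfbi circRNA was 3.88 and 3.42, and that of the Prmt8 circRNA was -2.33 and -2.68. Across 5250 host genes, which are not independent replicates, the fold change of the summed circRNA counts and that of the host gene had a Spearman correlation of 0.62. Both fold changes come from the same libraries, and splits of the libraries that mix the groups gave 0.348 to 0.49.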

Additional observations from a re-analysis of the deposited data

How the results depend on the processing

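Most counts depended on the settings, the settings added after seeing the data being lane 8, reference-class isoforms, class = isoforms, robust or unmoderated tests, other circRNA scalings and sums, and Gene Ontology; the cause was not tested. For genes past the threshold (24), no filter gave 0, median-ratio scaling 8, quantile normalization 9, array weights 165 (149 higher, 16 lower), all lanes as a covariate 0, lane 8 as a covariate 273, no lane 8 libraries 8 (4 higher, 4 lower), reference-class isoforms 149 and an unmoderated test 0. Leaving out 1 library gave 0 to 26. For lncRNA genes past the threshold (0), array weights gave 4, lane 8 as a covariate 9 and reference-class isoforms 4. For fixed lists (25), an estimated correlation gave 3, fry 15, array weights 20, and 1 library left out 16 to 26. Array weights ended the calls for antigen presentation (adjusted p = 0.0714), erythrocytes (0.184), excitatory neurons (0.0546), inhibitory neurons (0.0813), ion channels (0.181) and homeostatic microglia (0.152). For isoforms past the threshold (186), pseudocount 0.1 gave 303, no filter 17, a mean FPKM of at least 2 gave 17, median-ratio scaling 114, quantile normalization 37, array weights 2658, lanes 0, lane 8 as a covariate 0, no lane 8 libraries 0, class = isoforms 19, an unmoderated test 17, and 1 library left out 5 to 413. For isoform usage genes past the threshold (0), pseudocount 1 gave 5, no filter 153, median-ratio scaling 6, quantile normalization 11, array weights 3587, lanes 3, lane 8 as a covariate 18, no lane 8 libraries 172, and 1 library left out 0 to 47. For circRNAs past the threshold (0), DESeq2 gave 251 and lanes 75. For GO terms past the threshold (148, Gene Ontology), an estimated correlation gave 0, array weights 53, no lane 8 libraries 64, and 1 library left out 39 to 204. The correlation of circRNA and host fold changes was 0.54 to 0.665 with 1 library left out. The ratio of circRNA totals was 0.726 to 0.996 in the settings run, and that of circRNA numbers 1.01 to 1.06. Both kept their side of 1, but came close to it. Without the Ss18 circRNAs the ratio of totals was 0.984. These held 38.1% of the counts in sham replicate 2, 23.2% in TSCI replicate 2 and 17.4% in sham replicate 3. In the other libraries they held 0.4% to 2.1%.

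The replicate number as a block gave 305 genes past the threshold (295 higher), 12 lncRNA genes, 1 isoform and 1 usage gene. The labels do not say that numbers pair libraries. Deviations from the group means correlated at 0.4, 0.21 and 0.09 in same-numbered pairs at gene level, and TSCI replicate 2 correlated best with sham replicate 3 (0.3), so the numbers are not taken as pairs.

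Direction changed only in genes and lists that did not pass. In log2 fold change, Cd79a was -0.22 and Cd79b -0.01 with quantile normalization; with array weights Cacna1e was 0.2, Cd79b -0.59 and Mbp 0.14; Cd79b was -0.58 with lanes as a covariate. With no lane 8 libraries Slc18a3 was -0.22 and Mbp 1.08, and from reference-class isoforms Slc1a3 was 0.05. With 1 library left out, Cd79b ranged from -0.3 to 0.93, Mbp from -0.88 to 0.99, Gfap from 0 to 1.57, and Slc32a1 from -1.37 to 0.05. Camera turned direction for the myelin list with median-ratio scaling (adjusted p = 0.849), array weights (0.973) and lanes (0.571), and for the cholesterol list with no filter (0.883) and, with no lane 8 libraries, 0.337, and the ependymal list 0.689. Adjusted p with 1 library left out was 0.4 to 0.935 for myelin, 0.197 to 0.991 for cholesterol and 0.0203 to 0.88 for ependymal genes. Sham replicate 2 had the most tested genes at 0 (3765), and TSCI replicate 1, with the fewest aligned bases, the fewest (664).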

Other observations

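The tests on Gene Ontology terms, blood, and the splits of the libraries for genes, isoforms, isoform usage, lists and terms were chosen after the results were seen; those on lanes, scaling, linear reads and circRNA splits were not. Of 1833 Gene Ontology terms, 148 passed by camera, 122 higher and 26 lower in TSCI, and 0 with an estimated correlation. Genes of the nuclear nucleosome had a median log2 fold change 1.86 above that of all genes; many are histone genes with near-identical copies. The 36 tested genes of respiratory chain complex I in mitochondria had a median of -1.14 relative to all genes, and 31 of them lay below that of all genes (camera, adjusted p = 0.000135; adjusted p = 0.999 with an estimated correlation). Their median log2 fold change was -0.16 within lane 8 and -0.88 within lane 1. The number of terms was 81, 91 and 39 without TSCI replicate 2, TSCI replicate 3 and sham replicate 1.

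The higher values of the macrophage, phagocyte and chemokine lists in TSCI were weighed against lanes and blood. Lanes as the whole cause would put their median at or below that of all genes in a lane, but the lower of the 2 within-lane medians was 2.19 above it, with 54 and 50 of 55 members above the all-gene median in lanes 8 and 1. Blood left in the tissue may add to them: the erythrocyte list lay 1.24 above all genes, against 2.18 for the 3 lists. Hba-a1 was higher in every TSCI library than in every sham library and Hbb-bs was not (24678 FPKM in sham replicate 2, 2093 in TSCI replicate 1), so this stays open. An effect of injury on cells of the cord stays open too.

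More genes were higher than lower in TSCI, 88% of those at an unadjusted p under 0.05. Scaling of FPKM by a few abundant RNAs may account for part of this. The 10 most abundant isoforms took 11.4% to 52.0% of a library's FPKM, and the share of higher genes was 70% after median-ratio scaling and 59.9% after quantile normalization. Bounds for and against scaling as the cause were set for median-ratio scaling only, and its value lies between them. The value after quantile normalization lies just inside the range set for scaling as the cause. The explanation therefore stays open, as does a biological one.

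The fold changes of circRNAs and host genes had a Spearman correlation of 0.62 across genes. Splits of the libraries that mix the groups gave 0.348 to 0.49, so a value near 0 was not to be had and the correlation decides nothing on its source. In all 38178 comparisons of nested circRNAs with a shared start, the longer had at least the count of the shorter. That argues against counts made only of reads over each circRNA's own back-splice junction. Linear reads counted as circRNA reads may therefore be a source, and so may a shared change in transcription of the host gene. The share of each was not tested and stays open.

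The 6 libraries make 10 splits into 3 and 3, which cannot give a share under 0.05. The real split gave 24 genes and the highest other 3, 186 isoforms and 120, 25 lists and 17, 148 Gene Ontology terms and 115, and a host correlation of 0.62 and 0.49; in each of these 1 split, the real one, reached the real value. For lncRNA genes (0 and 0), isoform usage (0 and 41) and circRNAs (0 and 0) all 10 splits did. The 120 isoforms and 41 usage genes came from setting TSCI replicates 1 and 3 with sham replicate 1, and the 115 terms from a split that puts both lane 8 libraries on one side, which points to a structure of the libraries beside the groups. Within lane 8 and lane 1 the 3 immune lists were 2.23 and 2.19 above all genes.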
